A study of Mus musculus with 8 samples.

How the data were processed

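RNA was measured in 8 libraries from 4 mouse pancreatic cancer organoid lines, each with a vehicle culture and a 4-OH-tamoxifen culture. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into stranded libraries. The deposited values are raw read counts per gene, whole numbers with 1 column per library and no normalization or filter visible in the values. The submitters' processing notes list STAR 2.5.4a, featureCounts 1.6.3 and DESeq2 1.22.2, and they list GRCh38, a human genome build, although all 53801 gene identifiers in the deposited table are mouse Ensembl identifiers. The annotation release and the strand setting of the counting are not given in the sources used here, so overlapping and antisense genes, and reads shared between paralogs, cannot be separated with certainty.

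Groups and line names were taken from the sample titles, and columns were matched to samples by the library names that the titles hold. Gene symbols were found for 53620 of 53801 identifiers, and the other 181 held at most 0.0564% of the counts of a library. Symbols, biotypes and coordinates came from GENCODE mouse release 21 on GRCm38 by identifier. There were 0 rows without a gene and 0 unmapped columns. Counts of pairs of libraries differed by 17.4 to 221 times the sampling noise (chi-square per degree of freedom), so none was a repeat deposit. Depth was 12787611 to 18106210 counts per library, and intervals given for ratios cover counting error only.

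Same-named libraries come from the same organoid line, which pairs them. As a check, the deviations from the group means correlated within the pairs at 0.762, 0.695, 0.649 and 0.369 across genes. Each was higher than with any library of another line in the opposite group, the only ones compared. The margin was smallest in SC1956, at 0.369 against 0.296. By chi-square, which keeps the group difference, SC1640 and SC1693 libraries were nearest to their own pair (45.3 and 17.4). The Hnf4a-positive SC1853 library was at 83.75 to its pair, but 58.2 and 61.9 to Hnf4a-negative SC1693 and SC1956. The Hnf4a-negative SC1956 library was at 61.5 to its pair and 56.7 to Hnf4a-negative SC1693. The pairing rests on the line names in the titles. The main test was therefore edgeR 4.0.16 (R 4.3.3) with TMM factors (0.901 to 1.05) and the line as a block, as fixed from the series' mention of isogenic lines. The filter was filterByExpr with a minimum count of 10 and a minimum total of 15, which left 14676 genes. The quasi-likelihood fit had 3 residual degrees of freedom, a common dispersion of 0.0644 and 3.51 prior degrees of freedom. The SE of a fold change is its size divided by the square root of the F statistic. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Within-line differences used log2 CPM with a prior count of 2, and shares of variance are sums of squares of these values.

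A set of 31 gene lists with 595 genes was written from general knowledge before the data were examined, as were the groups, design, alternatives and naming rule. Of these genes 593 had an identifier and 415 were tested. Lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, again with the correlation estimated, and with fry. Adjustment ran over the 31 lists. Members adjusted over a list alone were adjusted over its tested genes, with no correction over the lists. A gene can therefore be counted in several lists. The named genes were Hnf4a, Six1 and Six4, the 10 largest changes per direction past the threshold with an average log2 CPM of at least 1 and the same direction in all lines, leaving out predicted genes and pseudogenes, and per list up to 4 members past the threshold, or the 2 most abundant where fewer than 2 passed.

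The alternatives were no block, DESeq2 1.42.0 with the line as a term, RLE, upper quartile or no factors in edgeR, no filter beyond 1 count, a filter of 1 CPM in all libraries of a group, limma-voom, a test against a 1.5-fold change, mitochondrial genes and the 20 most abundant genes left out, and each line left out. For the variance shares they were genes with a mean CPM of at least 10 and each line left out. The tests were tried on simulated data, 5 sets with 200 changed genes among 14676 in the Hnf4a-negative against Hnf4a-positive design. For 2-fold changes edgeR recovered 42.6%, limma-voom 44.2% and DESeq2 63.4%, and for 4-fold changes 85.2%, 86.4% and 89%. False calls were 5.75% of edgeR's, 7.9% of limma-voom's and 21.4% of DESeq2's. Each simulated change was equal in all 4 lines, so these shares need not hold for changes that differ between lines. In the data, larger changes missed edgeR's threshold, such as Tff3 at -6.31 (edgeR adjusted p = 0.1445) and Nlrc4 at -3.52 (0.0980). The list tests called a changed list in 5 of 5 sets and an unchanged list in 0 of 5. Simulated genes were drawn independently, whereas the estimated correlation was 0.663 in the cholesterol list, for example. These counts therefore do not show how often the preset-correlation test calls an unchanged list whose members move together. Splits of the libraries into other groups were refitted, as were fits of 2 or 3 lines alone for 3 of the lists, and random lists were drawn 10000 times from 20 bins of expression.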

Results

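The data were read counts per gene from 8 RNA libraries of organoids, 3D epithelial cultures grown in matrix, derived from mouse pancreatic cancer. HNF4A, encoded by Hnf4a, is a nuclear receptor transcription factor of endoderm-derived epithelia, and the comparison asked which transcripts differ when Hnf4a is deleted after a tumor has formed. Each of 4 organoid lines (SC1640, SC1693, SC1853 and SC1956) gave a pair of libraries. The first culture of the pair received vehicle and kept Hnf4a (the Hnf4a-positive group, n = 4). The other received 4-OH-tamoxifen, the active tamoxifen metabolite that switches on tamoxifen-dependent Cre recombinases, for 72 h to remove the gene (the Hnf4a-negative group, n = 4). No library received 4-OH-tamoxifen and kept Hnf4a. In every comparison below, effects of the agent or of Cre activity therefore cannot be told apart from the loss of Hnf4a. The medium held 50% of the L-WRN supernatant, which supplies Wnt, R-spondin and noggin. The labels do not say whether each line came from a different animal, so the p-values below measure the spread between lines as named. The Hnf4a-positive libraries held 12787611, 18007360, 18057301 and 18106210 counts and the Hnf4a-negative libraries 14675440, 15656832, 17845482 and 13996661, in the order of lines given above. Fold changes are Hnf4a-negative over Hnf4a-positive within lines, on the log2 scale, with the standard error (SE) of the fit.

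Hnf4a itself (ENSMUSG00000017950, a protein-coding gene on chromosome 2 from 163506808 to 163572910, plus strand, GRCm38) was lower in the Hnf4a-negative library of every line. Its level was 86.6 ± 17.9 CPM (counts scaled to a common library total, SD, n = 4) with vehicle and 20.3 ± 6.60 CPM (SD, n = 4) after 4-OH-tamoxifen, a log2 fold change of -2.13 (SE 0.138, edgeR adjusted p = 0.0136). Raw counts went from 710 to 158 in SC1640, from 1577 to 356 in SC1693, from 1877 to 497 in SC1853 and from 1707 to 308 in SC1956. The within-line log2 differences were -2.48, -1.93, -1.96 and -2.15. The counts cover the whole gene and the deleted exons are not given in the sources used here, so part of the remaining reads can come from outside the deleted part. Without the pairing by line, the fold change of Hnf4a was -2.09 and its edgeR adjusted p was 0.260. The adjusted p was 0.0987 without SC1693, 0.0766 without SC1853, 0.0510 without SC1956 and 0.0315 without SC1640, with fold changes between -2.19 and -2.01.

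The line of origin was the main difference between libraries. It took 74.4% of the variance of log2 CPM over 14676 genes, against 10.7% for the treatment and 14.9% for the residual. These shares are not divided by degrees of freedom, of which the line has more than the treatment. Both SC1640 libraries stood apart from the other 6 on the first principal component, which held 51.9% of the variance. Without SC1640 the shares were 61.0% for the line, 19.4% for the treatment and 19.6% for the residual.

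**Figure D1:**
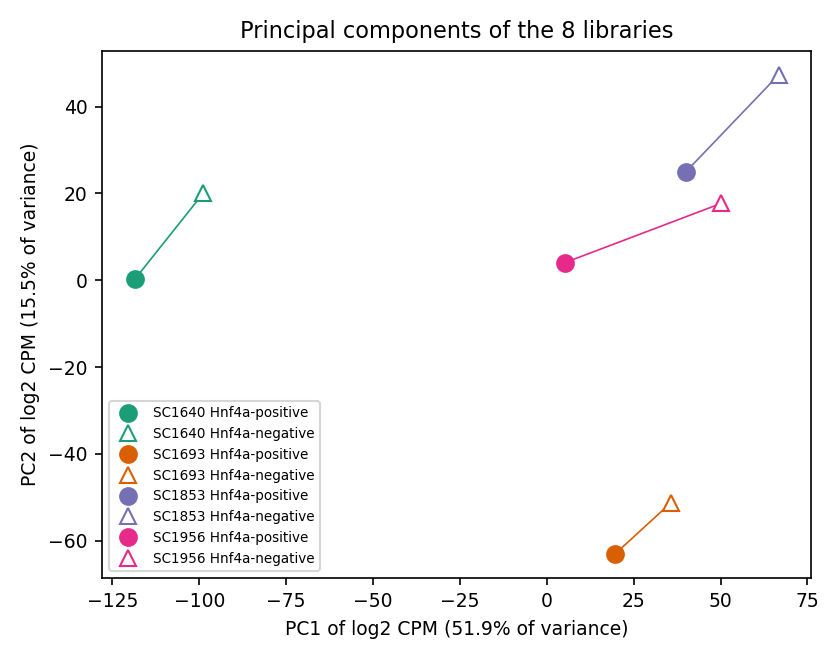
Principal components of log2 CPM over 14676 genes, with each axis labelled by its percent of variance. Filled circles are Hnf4a-positive and open triangles Hnf4a-negative libraries, and a line joins the pair of each organoid line. Both SC1640 libraries lie at -118.6 and -98.9 on the first component, and the other 6 lie between 5.11 and 66.8.

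Apart from Hnf4a, 6 genes passed the threshold over all genes, all lower and lower in 4 of 4 lines: Lgals2, Ms4a8a, Apob, Ces2c, Clca1 and Krt23. Lgals2, which encodes a galectin of the gastrointestinal tract (chromosome 15, 78850860 to 78855529, minus strand), went from 609, 952, 472 and 807 counts to 0, 8, 3 and 4, with a log2 fold change of -7.49 (SE 0.473, adjusted p = 0.0136). The counts of Lgals2 summed over the 4 libraries of a group, per summed TMM-scaled library size, were 182 times higher with vehicle, with an exact 95% counting interval of 110 to 326. Ms4a8a, a membrane protein gene (chromosome 19, 11067471 to 11081102, minus strand), went from 225, 16, 37 and 181 counts to 2, 1, 1 and 1, the same ratio of summed counts being 88.4 with an interval of 37.6 to 274 (edgeR adjusted p = 0.0391). Both intervals cover counting error only.

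Apob, the structural protein of chylomicrons and other lipoproteins (chromosome 12, 7977648 to 8016835, plus strand), fell from 23.4 ± 18.7 to 0.647 ± 0.244 CPM, a log2 fold change of -4.89 (SE 0.386, adjusted p = 0.0292). Ces2c, a carboxylesterase (chromosome 8, 104847068 to 104854483, plus strand), fell from 25.2 ± 33.0 to 1.74 ± 2.55 CPM (log2 fold change -3.97, SE 0.266). Ces2c lies among near-identical Ces2 genes that can share reads, so its level is uncertain. Clca1, a secreted goblet cell protein (chromosome 3, 145003817 to 145032776, minus strand), fell by 3.55 on the log2 scale (SE 0.294) from levels that ranged between lines from 60 to 28136 counts. Krt23, an epithelial keratin (chromosome 11, 99477974 to 99493137, minus strand), fell from 75.9 ± 11.1 to 15.3 ± 4.34 CPM (log2 fold change -2.34, SE 0.198, adjusted p = 0.0306).

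**Figure D2:**
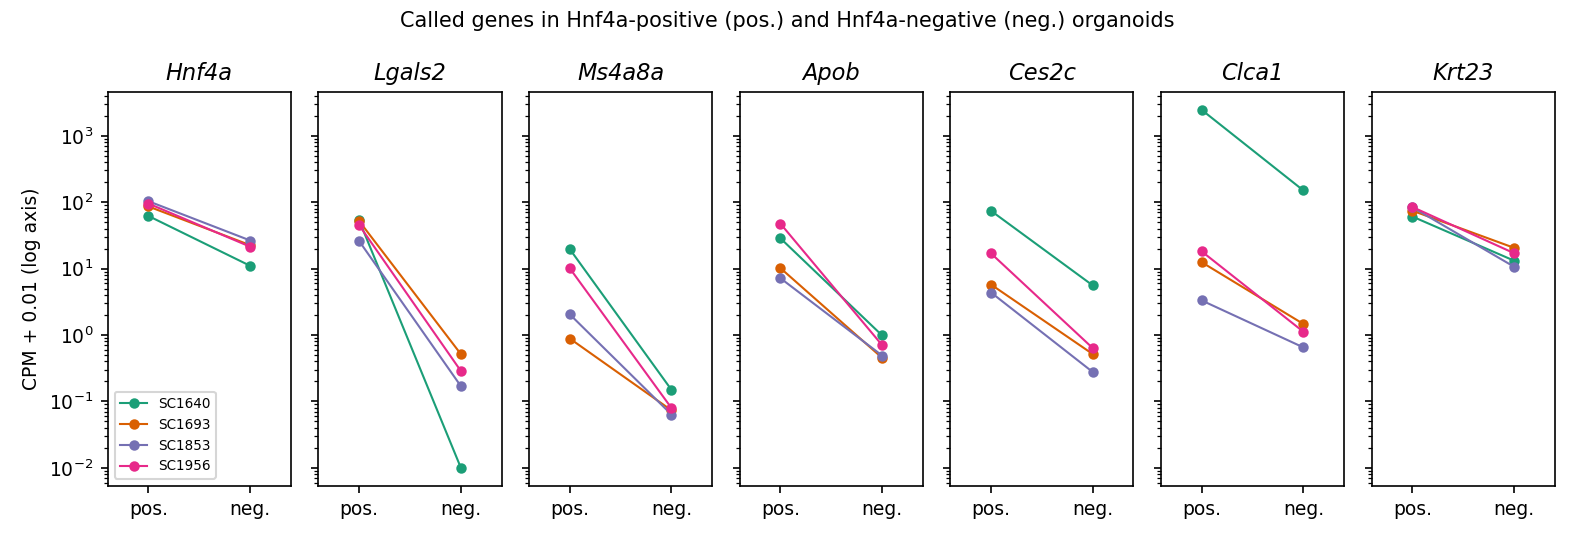
CPM of the 7 called genes on a log axis, with 0.01 added, in Hnf4a-positive (pos.) and Hnf4a-negative (neg.) organoids. Each point is a library and each line joins the pair of an organoid line. All 7 genes are lower in the Hnf4a-negative library of all 4 lines, and SC1640 has 0 counts of Lgals2 in its Hnf4a-negative library.

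No gene passed the threshold as higher in edgeR's quasi-likelihood test, although 657 genes were higher and 825 lower at an unadjusted p under 0.05. The count of higher genes was 0 in limma-voom and 157 in DESeq2. The count of lower genes was 7 in edgeR, 10 in limma-voom (6 shared with edgeR) and 278 in DESeq2 (7 shared). Without the pairing by line, 2 genes were lower, and leaving out SC1693 or SC1853 left 0 lower genes, while 6 genes were called without SC1640 and 4 without SC1956, of which 2 and 3 were among the 7. In every such fit the 7 genes had lower point estimates.

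Genes that define the classical, gut-like subtype of pancreatic cancer were lower in the Hnf4a-negative organoids. Of the 14 measured orthologues of the Moffitt classical signature, all 14 had lower point estimates and 7 fell when adjusted over the list alone, while 0 passed over all genes (6 of 14 fell in DESeq2). The gut lectin Lgals4 went from 795 ± 425 to 188 ± 287 CPM (log2 fold change -3.26, SE 0.664), the goblet cell peptide Tff3 from 103 ± 178 to 0.572 ± 0.507 CPM (-6.31, SE 0.976) and the gastric peptide Tff1 from 425 ± 803 to 27.0 ± 37.8 CPM (-2.54, SE 0.594). Tspan8, the other member named by abundance, had a log2 fold change of -0.52 (SE 0.188) and an adjusted p of 0.424. The list was lower in the preset-correlation camera test (adjusted p = 4.09e-13) and in fry (adjusted p = 0.0480), and its adjusted p was 0.126 with an estimated correlation. The fry call was lost whichever line was left out (adjusted p 0.125 without SC1640, 0.158 without SC1693, 0.107 without SC1853 and 0.163 without SC1956) and without the pairing (0.317). Of 17 measured Collisson classical orthologues, 7 fell when adjusted over the list alone and 0 over all genes. That list shares the measured members Tff1, Tff3, Lgals4, Tspan8 and Agr2 with the former, and its camera adjusted p was 3.05e-12, or 0.126 with an estimated correlation. The 7 Collisson members became 4 without SC1853 and 4 without SC1956, and without the pairing 1 of them and 2 Moffitt members passed. Tff3, Tff1 and the genes below that were named from tests over a list alone were chosen after their values were seen.

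The brush border of absorptive cells followed the same direction, in a list that is not separate from the classical ones. It shares Myo1a and Cdh17 with the Moffitt list and Pls1 and Muc13 with the Collisson list. Of 20 measured brush border members, 11 fell and 1 rose when adjusted over the list alone, and 0 passed over all genes. Vil1, which encodes the actin bundler villin, went from 122 ± 34.0 to 10.1 ± 8.34 CPM (log2 fold change -3.86, SE 0.374, adjusted p over all genes 0.0514). Myo1a, the brush border myosin, had a log2 fold change of -3.28 (SE 0.363) and the microvillus protocadherin Cdhr5 one of -3.48 (SE 0.474). The member that rose was the glucose transporter Slc5a1, at 0.935 ± 0.825 and 1.95 ± 1.86 CPM and higher in 3 of 4 lines. Ezr and Pls1, named by abundance, had log2 fold changes of -0.27 and -0.46. The list's median was -0.64 (camera adjusted p = 1.25e-10, fry adjusted p = 0.0464), and its adjusted p was 0.126 with an estimated correlation. Its fry call was also lost whichever line was left out (0.0592, 0.139, 0.177 and 0.163 without SC1640, SC1693, SC1853 and SC1956) and without the pairing (0.142). Without SC1853 the 12 members past the threshold became 7, and without SC1956 or without the pairing they became 4. Of 14 measured gastric mucous and neck genes, 4 fell when adjusted over the list alone and 0 over all genes: Sult1c2, Anxa10, Psca and Tff1. Anxa10 and Tff1 are also Moffitt classical members. The gastric list had a camera adjusted p of 2.02e-06, or 0.240 with an estimated correlation. Aqp5 and Tff2 had log2 fold changes of -0.55 and -1.63 (adjusted p 0.476 and 0.532). The 4 gastric members became 7 without SC1956 and 0 without the pairing, and the list's median within-line difference was -1.70 in SC1956 and between -0.69 and -0.51 in the other lines.

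Enzymes of drug and retinoid handling were lower in most members. Of 22 measured xenobiotic and retinoid metabolism genes, 21 had lower point estimates, 15 fell when adjusted over the list alone, 0 passed over all genes and 13 fell in DESeq2. Akr1c19, an aldo-keto reductase, went from 99.2 ± 30.0 to 47.3 ± 19.1 CPM (log2 fold change -1.10, SE 0.109, adjusted p over all genes 0.0514). The glucuronosyltransferase Ugt2b34 went from 728 ± 303 to 230 ± 217 CPM (-2.28, SE 0.450), the cytochrome P450 gene Cyp2c65 from 9.92 ± 14.2 to 0.144 ± 0.114 CPM (-5.42, SE 0.719) and the retinol carrier Rbp2 from 65.7 ± 47.1 to 20.9 ± 15.8 CPM (-1.61, SE 0.305). Gsta4, the most abundant member, had a log2 fold change of -0.79 and an adjusted p of 0.463. The Cyp2, Ugt and Gst families hold close paralogs whose reads can be split between members. The camera adjusted p was 9.19e-15, and 0.126 with an estimated correlation. Without the pairing by line, 1 member passed over the list alone. Of 9 measured hepatic and lipid transport targets of HNF4A, 3 fell when adjusted over the list alone (Apob, Cyp2c65 and the pyruvate kinase gene Pklr). Apob alone passed over all genes, and Cyp2c65 is counted in the xenobiotic list as well. Ttr and Ambp in the hepatic list had log2 fold changes of -1.36 and -1.38. The list's camera adjusted p was 3.78e-04, or 0.296 with an estimated correlation, and with a filter of 1 CPM in a whole group it was 0.0911 and the median 0.08 in place of -1.36. The hepatic median was 0.28 in SC1956 and below 0 in the other lines, the 3 members became 5 without SC1956, and Apob did not pass over all genes without SC1640, SC1693 or SC1853 or without the pairing. Nr1i2, the xenobiotic receptor gene, was the 1 of 22 measured endoderm transcription factors that fell when adjusted over the list alone, from 7.65 ± 4.08 to 1.96 ± 1.4 CPM (log2 fold change -2.08, SE 0.284). That list was not called (camera adjusted p = 0.105), but it was called as lower without SC1853 (0.006, or 0.460 with an estimated correlation), without the pairing (0.0280 and 0.351), with total counts (0.0420 and 0.405) and with no filter on low counts (0.0151 and 0.414).

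Cholesterol biosynthesis genes were lower together, unevenly between lines. Of 25 measured members, 24 had lower point estimates, 14 fell when adjusted over the list alone, 0 passed over all genes and 4 fell in DESeq2. Hmgcs1, which makes the precursor of mevalonate, went from 973 ± 354 to 610 ± 355 CPM (log2 fold change -0.81, SE 0.222), and the sterol demethylase gene Cyp51 from 821 ± 266 to 554 ± 339 CPM (-0.75, SE 0.232). The median within-line difference was -0.03 in SC1640, -0.30 in SC1693, -1.09 in SC1853 and -1.08 in SC1956. The camera adjusted p was 9.86e-14, and 0.352 with an estimated correlation. The 14 members became 0 without SC1693, SC1853 or SC1956, without the pairing, or with total counts in place of TMM factors, and 20 without SC1640.

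Mesenchymal transcripts were higher. Of 15 measured members of the mesenchymal and epithelial-mesenchymal transition list, 14 had higher point estimates, and 6 rose and 1 fell when adjusted over the list alone, with 0 past the threshold over all genes (4 rose and 1 fell in DESeq2). The intermediate filament gene Vim went from 19.8 ± 29.2 to 128 ± 194 CPM (log2 fold change 2.83, SE 0.450) and was higher in 4 of 4 lines. SC1956, at 63.1 and 419 CPM, made up most of both means. Vim went from 0.349 to 17.4 CPM in SC1640, from 10.2 to 32.3 in SC1693 and from 5.67 to 44.5 in SC1853. The receptor tyrosine kinase gene Axl went from 27.7 ± 32.2 to 85.2 ± 86.5 CPM (1.80, SE 0.337) and the N-cadherin gene Cdh2 from 4.05 ± 6.40 to 14.0 ± 17.6 CPM (2.11, SE 0.400). Tnc, Lgals1 and Twist1 also rose on that basis, and Serpine1, the plasminogen activator inhibitor gene, fell (log2 fold change -0.69, SE 0.195). Fn1 had a log2 fold change of 0.73 and an adjusted p of 0.532. The list's camera adjusted p was 1.22e-07, or 0.126 with an estimated correlation. The 7 members past the threshold became 3 without SC1956 and 0 without the pairing.

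Of 22 epithelial junction genes, 21 had lower point estimates but 0 passed over the list alone or over all genes. Krt8 and Krt18 had log2 fold changes of -0.49 and -0.16, and the list's camera adjusted p was 9.16e-07, or 0.296 with an estimated correlation. Of 18 targets of YAP, a growth-control coactivator, 2 rose when adjusted over the list alone (Axl and Ptpn14), and the list had a camera adjusted p of 1.24e-04, or 0.126 with an estimated correlation. Both YAP members were lost without SC1853, SC1956 or the pairing, and Axl is also a member of the mesenchymal list. Ccn2 and Myof had log2 fold changes of 0.38 and 0.15, with adjusted p of 0.424 and 0.853. The 11 measured Moffitt basal-like orthologues were not called (camera adjusted p = 0.467, or 0.0103 as lower without SC1693, where an estimated correlation gave 0.388): Lemd1 rose and the EGF receptor ligand Areg fell when adjusted over the list alone, while Krt7 and Ly6d had log2 fold changes of -0.19 and -1.75 with adjusted p of 0.804 and 0.419. Among 15 quasi-mesenchymal orthologues, Lox and Twist1 rose and Nt5e and Pmaip1 fell on that basis (camera adjusted p = 0.993), and the list's median was -0.02 and its mean 0.06. The 4 members became 2 without SC1640, SC1693 or SC1956 and 1 without SC1853. Fermt1 and Hk2 in it had log2 fold changes of -0.02 and 0.06.

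Interferon response genes were higher, most in a pair of lines. Of 25 measured members, 24 had higher point estimates, 9 rose when adjusted over the list alone, 0 passed over all genes and 10 rose in DESeq2. The chemokine gene Cxcl10 went from 1.07 ± 0.566 to 4.09 ± 1.78 CPM (log2 fold change 1.97, SE 0.387), the antiviral effector Rsad2 from 8.36 ± 8.48 to 24.0 ± 6.06 CPM (2.17, SE 0.620) and the tethering factor Bst2 from 42.8 ± 25.7 to 72.3 ± 27.1 CPM (0.91, SE 0.229). Irf9 had a log2 fold change of 0.48 and an adjusted p of 0.523. The median within-line difference was 1.93 in SC1640, 0.30 in SC1693, 2.37 in SC1853 and 0.36 in SC1956. Summed over the list, SC1640 went from 257.5 to 483.3 CPM and SC1853 from 212.5 to 764.1 CPM. SC1693 went from 810.8 to 967.9 CPM and SC1956 from 771 to 928.8 CPM. SC1640 and SC1853 thus started lower, and after 4-OH-tamoxifen stayed below the vehicle sums of SC1693 and SC1956. The camera adjusted p was 1.36e-10, and 0.360 with an estimated correlation. Without SC1853 the list's median fold change was 0.71 in place of 1.34, and the 9 members became 0 without SC1640, without SC1853 or without the pairing, 17 without SC1693 and 24 without SC1956. In SC1853 the mitochondrial share of counts also differed within the pair, 1.52% with vehicle and 2.58% after 4-OH-tamoxifen, and the Hnf4a-positive SC1640 library had the lowest depth (12787611 counts) and the fewest genes with a count (19982) of the 8 libraries.

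**Figure D3:**
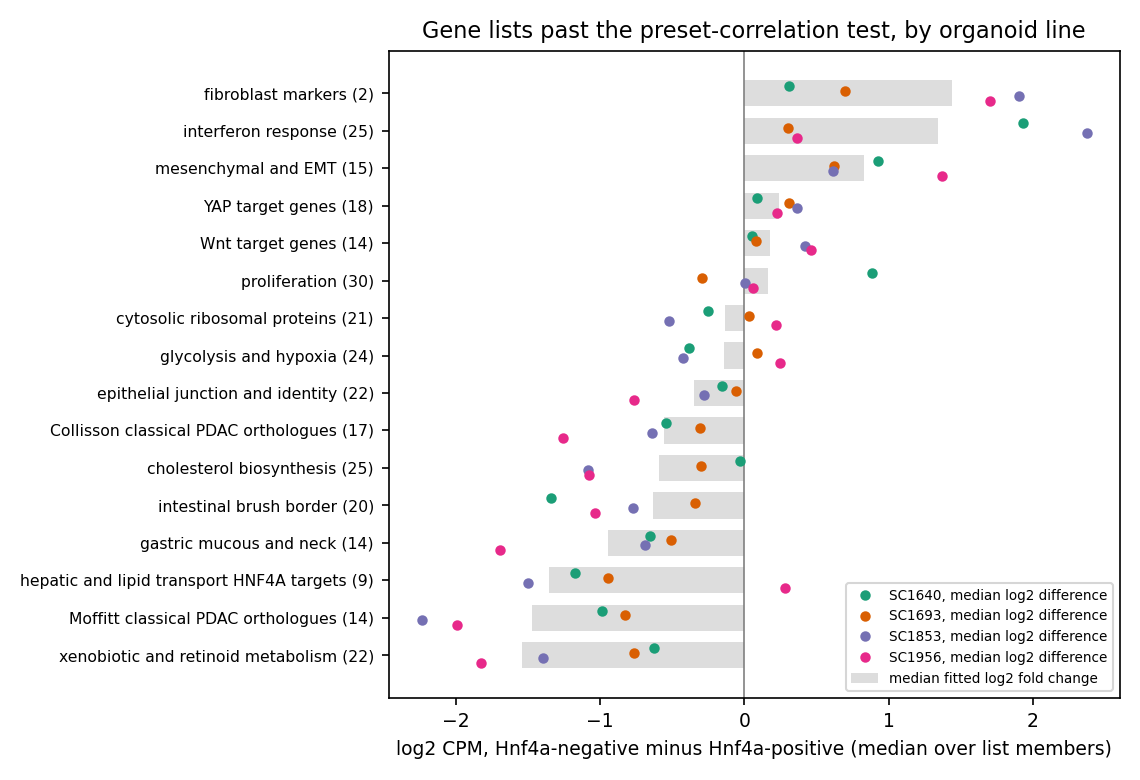
Median over the measured members of each list (their number in parentheses) for the 16 lists past the preset-correlation camera test. Bars give the median fitted log2 fold change and points the median within-line log2 difference, Hnf4a-negative minus Hnf4a-positive. The interferon response points reach 1.93 in SC1640 and 2.37 in SC1853 and lie at 0.30 and 0.36 in SC1693 and SC1956. None of these lists passed with an estimated correlation.

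Six1 and Six4, homeobox genes of embryonic development, were named in advance and did not pass. Six4 had 6.79 and 9.80 CPM (log2 fold change 0.45, SE 0.229, adjusted p = 0.572) and was higher in 3 of 4 lines. Six1 went from 0, 12, 16 and 0 counts to 14, 12, 15 and 1 (edgeR adjusted p = 0.762). Its counts were low and its lines unlike, with within-line log2 differences of 3.15, 0.18, -0.12 and 0.64. The rise in SC1640 is from a single pair. The 5 measured members of the list of Six1, Six4 and their Eya and Dach partner families had a camera adjusted p of 0.259. With no filter on low counts 9 members were tested and the list was called as higher (0.0233, or 0.265 with an estimated correlation). Eya2 and Eya3 had log2 fold changes of -0.45 and 0.07.

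Several lists passed the preset-correlation test on small medians, whose sign differed between lines except for the Wnt targets. Cytosolic ribosomal proteins had a median of -0.13 over 21 genes (camera adjusted p = 0.0129, or 0.741 with an estimated correlation), glycolysis and hypoxia -0.14 over 24 (0.0162 and 0.741) and proliferation 0.17 over 30 (0.0167 and 0.741), each with 0 members past the threshold on any basis. The proliferation median was 0.89 in SC1640 and -0.30 in SC1693, and without SC1640 it was -0.06 with an adjusted p of 0.290. Without SC1853 the ribosomal protein median was -0.0017 and that of glycolysis -0.043, with adjusted p of 0.931 and 0.552. The ribosomal call was also lost without SC1640 (adjusted p 0.191), as was that of glycolysis (0.421). Mki67 and Top2a had log2 fold changes of 0.47 and 0.39, Pkm and Aldoa of -0.08 and -0.18, and Rplp0 and Rpl4 of -0.12 and -0.09. The 14 measured Wnt targets had a camera adjusted p of 0.00686, or 0.442 with an estimated correlation and 0.195 without SC1956, with a median above 0 in 4 of 4 lines, 0 members past the threshold and log2 fold changes of 0.21 for Cd44 and -0.04 for Ephb2.

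The remaining lists of tumor cell genes were not called. Camera adjusted p values were 0.278 for pancreatic duct markers (Krt18 -0.16, Spp1 0.38), 0.0914 for estrogen receptor response (Areg and Tff1 fell over the list alone, and Ltf and Ccnd1 had log2 fold changes of -0.46 and 0.09) and 0.483 for MAPK output (Etv5 rose and Areg fell over the list alone, with Epha2 at -0.23). They were 0.0914 for the unfolded protein response (Hspa5 -0.13, Hsp90b1 -0.02), 0.0522 for replication-dependent histones (Hist1h1c -0.27, Hist1h1e -0.23) and 0.505 for mitochondrially encoded transcripts (mt-Co1 -0.11, mt-Rnr2 0.04). The p53 list had an adjusted p of 0.580, with Pmaip1 and Btg2 lower over the list alone and Plk2 at 0.07, and its median of 0.02 had the opposite sign to its mean of -0.07 and its test. Both p53 members were lost whichever line was left out. Without SC1693 the estrogen list was called as lower (adjusted p 0.00712), without SC1640 the unfolded protein response (0.00137) and the histones (0.0115), without SC1956 the histones (0.00251) and without SC1853 the mitochondrial transcripts (0.00398). With an estimated correlation these fits gave 0.374, 0.355, 0.612, 0.290 and 0.308. The histones were also called as lower with total counts (0.0464, or 0.559 with an estimated correlation), with no filter on low counts (0.0136 and 0.436) and without the pairing (0.0347 and 0.474), the unfolded protein response with no filter (0.0205 and 0.562) and the duct markers without the pairing (0.0476 and 0.280). Areg or Tff1 was lost from the estrogen list without SC1853, and the 2 MAPK members became 0 without SC1853 and 1 without SC1956. In the endoderm list, Onecut2 and Klf5 had log2 fold changes of -0.33 and -0.0049. The mitochondrial median was 1.27 in SC1853 and between -0.25 and -0.15 in the other lines, and the mitochondrial share of counts in SC1853 went from 1.52% to 2.58%.

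Few markers of other cell types could be tested. Of 16 fibroblast markers 2 could be tested. Col5a1 rose when adjusted over the list alone, from 0.423 ± 0.140 to 2.24 ± 2.25 CPM, but not over all genes (edgeR adjusted p 0.307). Pdgfra had a log2 fold change of 0.83 and an adjusted p of 0.644. The fibroblast list had a camera adjusted p of 0.0419, or 0.323 with an estimated correlation, 0.341 without SC1693, 0.124 without SC1956, 0.0544 with total counts and 0.0514 with upper quartile factors. Col5a1 did not pass without SC1693 or SC1853. The abundant fibroblast transcripts Col1a2 and Lum had 0 counts in all 8 libraries, which allows up to 3 counts per library, and Col1a1 had 0 to 30. Leukocyte (3 tested, camera adjusted p = 0.807), endothelial (3 tested, 0.630), acinar (1 tested, 0.228) and endocrine (2 tested, 0.921) markers were not called. Flt1 rose over the endothelial list alone (log2 fold change 0.81, edgeR adjusted p 0.339 over all genes) but not without SC1640 or SC1956. Esam, Cd14, Cd68, Cela1, Insm1 and Chgb had log2 fold changes of -0.21, -0.03, -0.10, -0.58, 0.85 and -0.44. The medians of the endothelial and leukocyte lists were -0.21 and -0.03, although their means and tests were positive.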

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

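The tests of explanations for the mesenchymal, interferon and cholesterol genes and the count of splits for fry were chosen after the result was seen. Of 127 groups of 4 values looked at, 7 held a value far from the other 3, where chance gives about 1 in 20, or 6.35. The Hnf4a-positive SC1640 library had 12.79 M counts against 18.01 to 18.11 in the others, and 19982 genes with a count against 21855 to 22115. In the Hnf4a-negative group, Six1 in SC1956 stood at a log2 CPM of -2.37 against -0.18 to 0.13, which is 1 count. Clca1 in the Hnf4a-negative SC1640 library stood at 7.23 against -0.39 to 0.66. The within-line difference of Eya2 was -2.37 in SC1956 and between -0.10 and 0.25 elsewhere. The median difference of the gastric mucous and neck list was -1.70 in SC1956 and between -0.69 and -0.51 elsewhere. That of the mitochondrially encoded transcripts was 1.27 in SC1853 and between -0.25 and -0.15 elsewhere.

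Splits of 4 pairs are too few for a share under 0.05. The blocked edgeR test called 7 genes in the real split, and of the 32 splits that could be fitted 1, the real one, reached 7. Only 8 splits part all 4 pairs, so their share cannot go below 0.125. The highest of the other 7 was 0. The 24 splits that part 2 pairs hold 12 that repeat the treatment order in 2 lines, so they carry part of it and cannot serve as chance, and the highest of these called 5. For DESeq2 the real split called 435 genes, and 1 of 32 splits reached that. The highest other was 327, among those repeating the treatment in 2 lines, or 40 among splits parting all pairs. The split with 40 keeps the treatment order in every line but 1, so it carries part of it. Splits that oppose the order in equal numbers of lines called up to 78. Without the block, 4 of 35 splits reached the real count of 2, the real one and the 3 that separate whole lines, with up to 4 genes. Those 3 carry the differences between lines, so they cannot serve as chance either. The remaining splits called 0 genes. All these fits ignore the pairing, so they cannot decide the question and chance is not excluded there.

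The preset-correlation camera test called 16 lists in the real split, and 11 of 32 splits, the real one included, gave as many, up to 18. The other 10 all repeat the treatment order in 2 lines. Splits parting all pairs gave up to 15, but those with 15 keep the treatment order in every line but 1, so they carry part of it. Splits that oppose the order in equal numbers of lines gave up to 10. Such splits are too few for a share under 0.05, so chance is not excluded for the number of lists called that way. Fry called 2 lists, with 1 of the 32 splits, the real one, reaching that and a highest other of 0. The splits that part all pairs are again too few for a share under 0.05.

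Mesenchymal genes were higher in Hnf4a-negative organoids with the preset correlation, but did not pass with an estimated one (adjusted p 0.126) or in fry (0.0573), and 6 of 15 members rose over the list alone and 0 over all genes. A change in 1 line alone is argued against, since at least 3 members were higher and past the threshold over the list alone whichever line was left out (7, 7, 5 and 3 without SC1640, SC1693, SC1853 and SC1956). The fibroblast list was called as higher on 2 tested markers (adjusted p 0.0419, or 0.323 with an estimated correlation), and the summed CPM of Col1a1, Col1a2, Col3a1, Dcn and Lum was higher in 4 of 4 lines. Fibroblasts in the cultures would bring these abundant transcripts, but the increase in their sum was at most 2.98% of that of Vim in a line, which argues against fibroblasts in the cultures as the main source, though not against a trace of them. What stays open is 4-OH-tamoxifen or Cre activity apart from the loss of Hnf4a, since 0 libraries had 4-OH-tamoxifen and kept Hnf4a, and it cannot be told apart from the loss of Hnf4a.

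Interferon response genes were higher with the preset correlation, but did not pass with an estimated one (adjusted p 0.360) or in fry (0.272), and the 9 of 25 members that rose over the list alone became 0 without SC1640 or without SC1853. Leukocytes in the cultures are argued against as the main source of these transcripts. The increase in the summed CPM of 7 leukocyte markers was at most 0.149% of that of the interferon list. That sum left out Cd14 and Cd68. Cd14 went from 160 to 216 CPM in SC1693 and from 134 to 192 CPM in SC1956. It was lower in SC1640 and SC1853, the lines with the larger interferon medians. Whether it was a change in lines SC1640 and SC1853 alone cannot be told apart: in edgeR on SC1693 and SC1956 alone 21 of 25 members had higher point estimates, but 0 passed over the list alone (lowest adjusted p 0.0902). The medians of 0.30 in SC1693 and 0.36 in SC1956 lay at the 99.99th percentile or above of expression-matched random lists, but each is from a single pair, and the members of a list can move together in a pair whatever the treatment does (the proliferation median was 0.89 in SC1640 and -0.30 in SC1693). Effects of the loss of Hnf4a and of 4-OH-tamoxifen or Cre stay open.

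Cholesterol biosynthesis genes were lower with the preset correlation, but did not pass with an estimated one (adjusted p 0.352) or in fry (0.227), and the 14 of 25 members that fell over the list alone became 0 without SC1693, SC1853 or SC1956. Whether it was a change in lines SC1853 and SC1956 alone cannot be told apart: in edgeR on SC1640 and SC1693 alone 21 of 25 members had lower point estimates, but 0 passed over the list alone (lowest adjusted p 0.501). These 2 lines were unlike, with a median of -0.30 and 24 of 25 members lower in SC1693, below all random lists, and a median of -0.03 and 15 of 25 lower in SC1640, at the 75.92th percentile, each in a single pair. An effect of Hnf4a and effects of the agent stay open.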

How the results depend on the processing

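No setting here was chosen after the results were seen. The 7 called genes kept their direction in every alternative that fitted them. The count of higher genes was 0 in edgeR and limma-voom settings except with no filter on low counts, where it was 112, and it was 157 in DESeq2. The count of lower genes was 7, and 241 with no filter, 278 in DESeq2 and 2 without the replicate block (the paired fit being the main one), within 0 to 6 over fits that leave out a line. With no filter, 29135 genes were tested and the prior degrees of freedom went from 3.51 to 14.3, and no filter and DESeq2 gave 31.7% and 36.1% of calls as higher in place of 0%. The Hnf4a log2 fold change was -2.09 without the block (adjusted p 0.260, over alternatives 2.83e-32 to 0.260), and -2.19 to -2.01 over left-out lines, of which only the fit without SC1640 kept the call (adjusted p 0.0315). The number of lists called was 16, against 0 with an estimated correlation, 2 with fry, 20 with no filter, 14 with 1 CPM in a group, 15 to 17 over left-out lines and 15 to 17 in the other settings. The limma-voom and 1.5-fold settings use the same voom values for lists as the main setting, so their list tests are the main ones repeated. With no filter the endoderm (0.0151), histone (0.0136), unfolded protein response (0.0205) and Six1, Six4 and partner (0.0233) lists were called, with total counts the endoderm (0.0420) and histone (0.0464) lists, while the fibroblast call was lost with total counts (0.0544) and upper quartile factors (0.0514). Without the block, camera lost Wnt targets (adjusted p 0.164) and glycolysis (0.0739) and called endoderm factors (0.0280), duct markers (0.0476) and histones (0.0347), and no other list's call changed. With an estimated correlation these 3 had 0.351, 0.280 and 0.474. The share of variance by line was 61.0% to 77.0% and by treatment 11.4% to 19.4% over left-out lines. The cause was not tested for these. Depth limits genes near the floor, and for Six1 the lines also differed.

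Direction turned for named genes and lists that had not passed, and for the proliferation and ribosomal protein lists, which had. For a list the direction is that of its camera test, and the value given is its median, which did not always turn with it. Klf5 was 0.0011 in DESeq2, 0.0013 with RLE, 0.0053 with 1 CPM in a group and 0.00717 in limma-voom, where Esam was 0.012. With total counts Fermt1 was 0.038, Klf5 0.056, Ephb2 0.022, Hsp90b1 0.037, Cd14 0.027, and the endocrine test turned while its median went from 0.20 to 0.25. With upper quartile factors Fermt1 was 0.0025, Klf5 0.021 and Hsp90b1 0.0023. Without the block Onecut2 was 0.26, Hsp90b1 0.0202, Esam 0.10, Chgb 0.15, and the tests of the endocrine, endothelial and leukocyte lists turned to lower, with medians of 0.18, 0.10 and -0.12 in place of 0.20, -0.21 and -0.03. With no filter the quasi-mesenchymal and endocrine lists had medians of 0.018 and -0.47, and with 1 CPM in a group the leukocyte test turned to lower with a median of -0.058. Over left-out lines the ranges were Krt7 -0.34 to 0.017, Fermt1 -0.054 to 0.0041, Hk2 -0.13 to 0.22, Eya2 -0.71 to 0.11, Eya3 -0.034 to 0.18, Onecut2 -0.83 to 0.13, Klf5 -0.30 to 0.16, Plk2 -0.016 to 0.18, Ltf -1.09 to 0.016, Ccnd1 -0.0397 to 0.23, Ephb2 -0.073 to 0.023, Myof -0.013 to 0.33, Pkm -0.21 to 0.055, Hsp90b1 -0.18 to 0.056, Esam -0.84 to 0.23, Cd14 -0.22 to 0.29, Cd68 -0.28 to 0.15, Insm1 -0.0709 to 2.11, Chgb -1.74 to 0.71, mt-Rnr2 -0.29 to 0.23, Rplp0 -0.23 to 0.031 and Rpl4 -0.21 to 0.046. List medians ranged over -0.10 to 0.20 for quasi-mesenchymal, -0.059 to 0.34 for proliferation, -0.91 to 1.41 for endocrine, -0.22 to 0.15 for leukocyte, -0.23 to -0.0017 for ribosomal proteins, -0.18 to 0.27 for mitochondrial and -0.33 to 0.23 for endothelial genes. The mitochondrial list passed as lower without SC1853 (adjusted p 0.00398, or 0.308 with an estimated correlation). Some medians turned while the direction of the list's test stayed. That of the hepatic list went from -1.36 to 0.08 with 1 CPM in a group, that of MAPK output from -0.05 to 0.02 with total counts and that of the estrogen list from -0.15 to 0.02 without SC1853, and the p53 median was 0.02, 0.08 with total counts and -0.02 without SC1853. The other list tests and gene fits kept the direction of their test, 388 list tests and 821 gene fits with their side of the threshold. These hold the list tests of the limma-voom and 1.5-fold settings, which equal the main ones by construction. The fold changes of the 1.5-fold setting equal the main ones in the same way.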

Other observations

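Genes named here outside the fixed lists were chosen after their values were seen, while the inflammasome test was written before its result. Apart from Ces2c, none of the genes of this paragraph passed over all genes in edgeR. In the microvillus adhesion complex, which links brush border microvilli at their tips, Anks4b had a log2 fold change of -5.78 (SE 0.606, edgeR adjusted p = 0.0524) and Calml4 one of -4.66 (SE 0.480, adjusted p = 0.0524), each lower in 4 of 4 lines. The protocadherins Cdhr5 and Cdhr2 stood at -3.48 (adjusted p = 0.115) and -4.44 (adjusted p = 0.319), and the microvillus protein Eps8l3 at -3.98 (adjusted p = 0.133), while Myo7b, the tip myosin, stood at -0.69 (adjusted p = 0.594). Of the carboxylesterase genes near Ces2c, Ces2a had a log2 fold change of -5.97 (adjusted p = 0.0594) and Ces2g one of -0.69 (adjusted p = 0.279), both lower in 4 of 4 lines, with reads that paralogs can share.

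Nlrc4, Nlrp6, Naip2, Naip6 and Gsdmd, chosen after their values were seen, were each lower in 4 of 4 lines without passing over all genes in edgeR: Nlrc4 -3.52 (SE 0.432, adjusted p = 0.0980), Nlrp6 -2.68 (SE 0.610, adjusted p = 0.269), Naip2 -1.90, Naip6 -1.60 and Gsdmd -1.09 (SE 0.237). All 5 passed in DESeq2. A wider decrease of epithelial inflammasome genes was tested on 6 genes fixed before their values were seen, Naip1, Naip5, Casp1, Casp4, Il18 and Pycard. Of the 5 that could be tested 0 passed, and fewer than 3 had been set in advance as evidence against it. That bound was wrong, since Naip1 and Naip5 had log2 fold changes of -1.37 and -1.49, with SEs of 0.622 and 0.656. A missed threshold therefore does not show that they stayed level. These fold changes were near those of Gsdmd and Naip6 but less even between lines. Naip5 was higher in SC1640 (0.49), and its mean went from 30.2 to 36.9 CPM. Naip1 stood at -3.54 in SC1956 and between -0.94 and -0.32 in the other lines. Il18 stood at -0.62 (SE 0.225), and Casp4 and Pycard had higher point estimates (0.27 and 0.94). Whether the decrease is wider is left open. The Naip genes are near-identical, and their reads can be shared.

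Both SC1640 libraries had 0 counts of the Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y and 8191 and 4635 counts of Xist. The libraries of the other 3 lines had 860 to 2180 counts of each of these Y-linked genes and 1 to 6 of Xist. The libraries of each line thus share these markers. The counts argue against an animal shared by SC1640 and the other lines. Whether the other 3 lines share an animal stays open. These markers are alike in those 3 lines, so they cannot check the pairing among them.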
